A study of Canis lupus familiaris with 21 samples.

How the data were processed

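RNA sequencing was done on 21 libraries: 9 from prefrontal cortex and 12 from plasma EVs of young, old and CCD dogs. Per the labels, cortex libraries were made from polyadenylated RNA and EV libraries from total RNA after ribosomal depletion, and both were read as 150 bp pairs. Per the submitters' processing notes, reads were handled with STAR and DESeq2; the versions, the genome build, the annotation and the counting tool are not given in the sources used here. The authors deposited 1 table per tissue with a signal per gene or transposable element family, which its sheet calls normalized counts. Each table has 35803 features, of which 34981 are genes and 822 are families. Within a table every library has the same total, 23009609 in cortex and 35344491 in EVs, which equals the mean read total. Each value was found to be a whole number times a library factor, and dividing by it gave back whole reads for 100% of values with a tolerance of 0.01; for young cortex_353 the factor is near 1, so this test says little there. The recovered reads gave the depth of each library. Counting error is small for genes with many reads, where the spread between libraries limits the precision. It is larger for genes with few reads, such as H4C8 (9.73 to 17.1 normalised counts in old EVs) and FOSB (0 in CCD cortex_354). Of the gene symbols 95.4% were found in the RefSeq annotation of the assembly UU_Cfam_GSD_1.0, which was used for names and neighbouring genes alone.

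Genes with a mean normalised count of at least 10 over a table's libraries were tested, 19010 in cortex and 31728 in EVs, and so were 700 and 811 transposable element families, adjusted as a family of tests of their own. Values were tested as log2 of the normalised count plus 1 in R 4.3.3 with limma 3.58.1 (linear model over the 3 groups of a tissue, moderated with a trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The groups CCD, old and young were compared pairwise within each tissue. Fold changes are on the log2 scale with the standard error of the model, and means are normalised counts with their SD. Recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0. Before the data were examined 39 gene lists were fixed for cell types, disease pathways and possible sources of other cells. They were tested with camera, with a preset correlation of 0.01 and at least 5 measured members, again with the correlation estimated per list, and with fry. List values are the median log2 fold change of members less that of all tested genes, and a library's list score is the median over members of the log2 level relative to the mean of all libraries. Library measures were compared with exact two-sided permutation tests. The tests of transposable element families were added after the data had been seen.

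The genes named in the text were chosen by a rule fixed before the data were examined, with an addition stated below. Per comparison it takes genes that have a symbol, an adjusted p under 0.05 and groups that do not overlap. Where fewer than 5 pass in a direction, it adds the genes of smallest p up to 5 per direction, stated as not passing, and this was so in every comparison. It also takes up to 4 members of smallest p from each list, and GFAP, APOE, APP, MAPT and TREM2 whatever their values. Members that passed when adjusted over their list alone were taken as well, which is not part of the rule fixed beforehand. Not every gene the rule takes is named.

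The tests were tried on simulated data with the real group sizes, changes planted in CCD and CCD tested against old. The spread was that estimated over all 3 groups of a tissue, young included. The fit of the compared groups alone was not tried in this way. At a planted change of 2-fold, 4-fold and 8-fold limma recovered 10.4%, 65.7% and 83.3% of changed genes in cortex and 4.48%, 52.2% and 86.4% in EVs, calling 6 and 4 unchanged genes. edgeR recovered 10.4%, 64.2% and 83.3% in cortex with 2 unchanged genes called. DESeq2 recovered 32.8%, 88.1% and 89.4% in cortex with 66 unchanged genes called, and 46 in EVs. A list planted with a 1.5-fold change was found in cortex at an adjusted p of 7.6e-08 with the preset and 0.0194 with an estimated correlation, and 0 of 39 other lists were called. The simulated genes were drawn independently of each other. This trial therefore cannot show how often camera with the preset calls unchanged lists whose members are correlated.

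Alternatives fixed before the data were examined were a pseudocount of 5, no filter and a mean of at least 50, quantile normalisation, scaling to counts-per-million, a fit of the compared groups alone, library weights, DESeq2, edgeR, leaving out each library in turn, and for the correlation of the tissues the numbers with both libraries. Alternatives chosen after seeing the data were thinning of every library to the shallowest, centring on the median gene, scaling to gene reads or to transposable element reads, the meningeal score or the level of LOC102156855 as a covariate, leaving out the 3 libraries high in meningeal markers, and leaving out or adding a term for the 3 numbers without a cortex library. All libraries and columns were used.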

Results

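RNA was sequenced from prefrontal cortex and from extracellular vesicles of plasma (EVs, membrane-bound particles released by cells) of companion dogs. The dogs were young, old, or had canine cognitive dysfunction (CCD), a decline of memory and behaviour in aged dogs that is studied beside Alzheimer's disease. Cortex gave 9 libraries, 3 per group, and EVs gave 12 libraries, 4 per group. A library is named here by its group and its label, which ends in a number. The numbers of the 9 cortex libraries recur among the EV libraries, while young EV_502, old EV_519 and CCD EV_523 have an EV library alone. The labels do not say that each number is a separate dog, so p-values of genes, families and library measures measure the spread between these libraries. Those of camera with the preset instead compare the members of a list with other genes, under an assumed correlation. Cortex libraries held 14.9 to 31.4 M reads. The CCD cortex libraries were the shallowest, at 17.4 ± 2.13 M reads (SD, n = 3) against 26.2 ± 1.79 M in old (n = 3), exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. EV libraries held 27.5 to 45.0 M reads. CCD EV libraries held 37.1 ± 2.77 M (SD, n = 4) against 31.0 ± 1.55 M in old (n = 4), exact two-sided permutation p = 0.0286, adjusted p = 0.514 over the 27 library measures tested in that tissue.

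The first comparison, CCD against old cortex, asks what sets the diseased brain apart from old brain (n = 3 libraries per group for every value). Genes of the synapse and of excitatory neurons fell relative to all other genes in CCD, while ribosomal protein, mitochondrial, complement and microglial genes rose. The median synapse gene was lower by a log2 change of -0.52 relative to all genes, and 35 of the 40 measured members had a negative change (camera adjusted p = 6.6e-06; adjusted p = 0.546 with an estimated correlation). SYT1, the calcium sensor of transmitter release, had a mean normalised count of 15185 in CCD and 30897 in old, a log2 fold change of -1.03 ± 0.30 (SE). GRIN1, the obligatory NMDA receptor subunit, had a log2 fold change of -0.96 ± 0.31, and NLGN1, a postsynaptic adhesion molecule, went the other way at 0.83 ± 0.24. Excitatory neuron markers had a median of -0.58 relative to all genes (camera adjusted p = 0.00459; adjusted p = 0.546 with an estimated correlation), with 13 of 14 members negative; the median was -0.37 without CCD cortex_354. Of these, 2 fell when adjusted over the list alone and 0 over all genes: TBR1, a transcription factor of deep-layer projection neurons, at -2.18 ± 0.53 (adjusted p = 0.0249 over the list alone), and SLC17A7, the vesicular glutamate transporter, at -0.96 ± 0.26 (0.0259). The inhibitory neuron markers did not pass (median -0.18, camera adjusted p = 0.133), although GAD1 and GAD2, which make GABA, had log2 fold changes of -1.42 ± 0.42 and -2.52 ± 0.77.

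Genes of the protein-making and energy machinery were higher in the CCD cortex. Cytosolic ribosomal protein genes rose by a median of 0.76 relative to all genes, positive in 79 of 80 members (camera adjusted p = 1.1e-19; adjusted p = 0.546 with an estimated correlation). They made up 3.18 ± 0.540% of gene reads in CCD and 1.99 ± 0.345% in old (SD, n = 3), exact two-sided permutation p = 0.1, adjusted p = 0.338 over 27 tests. The 6 measured mitochondrially encoded genes rose by a median of 1.14 (camera adjusted p = 2.1e-05; adjusted p = 0.546 with an estimated correlation), all 6 of them when adjusted over the list alone and 0 over all genes. CYTB, the cytochrome b of complex III, had a log2 fold change of 1.10 ± 0.37 and ND3, a complex I subunit, of 1.51 ± 0.58. The share of reads on these genes was 7.02 ± 1.34% in CCD and 3.38 ± 0.819% in old (SD, n = 3), exact two-sided permutation p = 0.1, adjusted p = 0.338 over 27 tests. Nuclear oxidative phosphorylation genes rose by 0.47, positive in 52 of 64 (camera adjusted p = 2.1e-05; adjusted p = 0.744 with an estimated correlation). NDUFB9 of complex I was at 0.71 ± 0.34 and SDHA, the catalytic subunit of complex II, at -0.58 ± 0.18.

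Immune genes were also higher in CCD than in old cortex. The microglia score was -0.49 to -0.30 in old libraries, -0.21 to 0.32 in CCD and 0.35 to 0.62 in young, so CCD lay between. Against young cortex, as given below, microglia and NF-kB genes were lower in CCD and the other immune lists of this paragraph were not called. Complement genes rose by a median of 0.69 (camera adjusted p = 9.7e-05; adjusted p = 0.546 with an estimated correlation). When adjusted over the list alone 2 of the 21 rose and 1 fell, against 0 over all genes: C3, the central complement protein, at 1.04 ± 0.27, its receptor C3AR1 at 1.21 ± 0.32, and the C5a receptor C5AR1 at -1.28 ± 0.34 (adjusted p = 0.0253 for each over the list alone). Microglia markers rose by 0.40, with 18 of 23 positive (camera adjusted p = 5.4e-04; adjusted p = 0.546 with an estimated correlation), among them FCER1G, an immune receptor adaptor, at 1.31 ± 0.38 and LAPTM5 at 0.91 ± 0.25. Disease-associated microglia genes (0.70, camera adjusted p = 0.00678), antigen presentation genes (0.66, 0.00123) and reactive astrocyte genes (0.55, 0.0218) rose too, each with an adjusted p = 0.546 with an estimated correlation. So did type I interferon genes (0.49, camera adjusted p = 0.00184; adjusted p = 0.626 with an estimated correlation) and inflammatory cytokine and NF-kB genes (0.56, 0.0190; adjusted p = 0.655 with an estimated correlation). Fibroblast and meningeal markers moved the same way, by 1.40 (camera adjusted p = 0.00678; adjusted p = 0.744 with an estimated correlation), as did endothelial markers by 0.33 (0.0289; adjusted p = 0.809 with an estimated correlation). The meningeal score was high in young cortex_353 (3.67), young cortex_377 (2.97) and CCD cortex_358 (2.88), and between -2.62 and -0.76 in the other 6 cortex libraries. Without CCD cortex_358 these immune, meningeal and endothelial calls ended, except those of complement (0.40) and microglia: the medians were then 0.56 for disease-associated microglia, 0.32 for antigen presentation, 0.31 for reactive astrocyte, 0.29 for interferon, 0.31 for NF-kB, 0.23 for meningeal and -0.03 for endothelial genes. The reactive astrocyte call also ended without old cortex_250 (0.39), the NF-kB median was 0.23, still called, without old cortex_264, and the endothelial call ended without old cortex_253 (0.22) or old cortex_264 (0.21).

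Among genes of Alzheimer's disease, the amyloid and tau pathway fell by a median of -0.25 relative to all genes, negative in 24 of 30 (camera adjusted p = 0.00161; adjusted p = 0.546 with an estimated correlation). When adjusted over the list alone 3 fell, and 0 over all genes: MARK4, a tau kinase, at -0.94 ± 0.23, CDK5R1, the activator of the tau kinase CDK5, at -1.66 ± 0.44, and PSEN2, a gamma-secretase subunit, at -0.92 ± 0.25 (adjusted p = 0.0409 for each over the list alone). APP, the amyloid precursor, had a log2 fold change of -0.73 ± 0.24 and MAPT, which encodes tau, of -0.61 ± 0.19 (limma adjusted p = 0.290 for both). GFAP, the astrocyte filament protein, was at 0.47 ± 0.24 (limma adjusted p = 0.374), the lipid carrier APOE at 0.47 ± 0.28 (0.428; 0.25 without old cortex_264) and the microglial receptor TREM2 at 0.05 ± 0.72 (0.978).

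Gene by gene, limma called 0 of the 19010 tested genes at an adjusted p under 0.05 in CCD against old cortex, with 758 higher and 2057 lower at an unadjusted p under 0.05. The edgeR count was 0 (unadjusted 2472, 1318 higher and 1154 lower) and that of DESeq2 162, of which 111 were higher (2980 unadjusted). Groups did not overlap in 34.5% of genes, where chance gives 10%. The genes of smallest p were STING1, a sensor adaptor of cytosolic DNA, with 387 ± 61.1 (SD) normalised counts in CCD and 136 ± 29.0 in old (log2 fold change 1.51 ± 0.30), WDR97 (1.24 ± 0.26), FER1L4 (1.26 ± 0.26), MYOM2 (1.60 ± 0.34) and MOV10, an RNA helicase that restrains retroelements (1.25 ± 0.27). On the lower side they included PPARD, a nuclear lipid receptor (421 ± 125 against 1202 ± 183; -1.54 ± 0.28), RBFOX3, the neuronal splicing factor known as NeuN (2211 ± 285 against 4288 ± 408; -0.96 ± 0.19), LRRC59 (-1.09 ± 0.21) and RNF168 (-0.96 ± 0.19), all with a limma adjusted p of 0.290. A fit of the 6 CCD and old libraries alone, planned before the data were examined, called 483 genes higher and 1295 lower, among them each of these 9 genes and SYT1, SLC17A7, TBR1, C3, APP and MAPT. Of gene list members this fit called 43 of 80 ribosomal protein genes higher, and of 40 synapse genes 17 lower and 1 higher. Its fold changes are those of the fit of 3 groups, where the young libraries also enter the estimate of spread. Young libraries were the least alike, with a Spearman's rho across genes of 0.908 to 0.934. Between CCD libraries it was 0.957 to 0.971 and between old libraries 0.982 to 0.985. Young cortex_353 and CCD cortex_358 had a rho of 0.978. The lower share of genes at an unadjusted p under 0.05 was 73.1% with limma and 60.4% after quantile normalisation. With edgeR more genes were higher than lower.

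**Figure D1:**
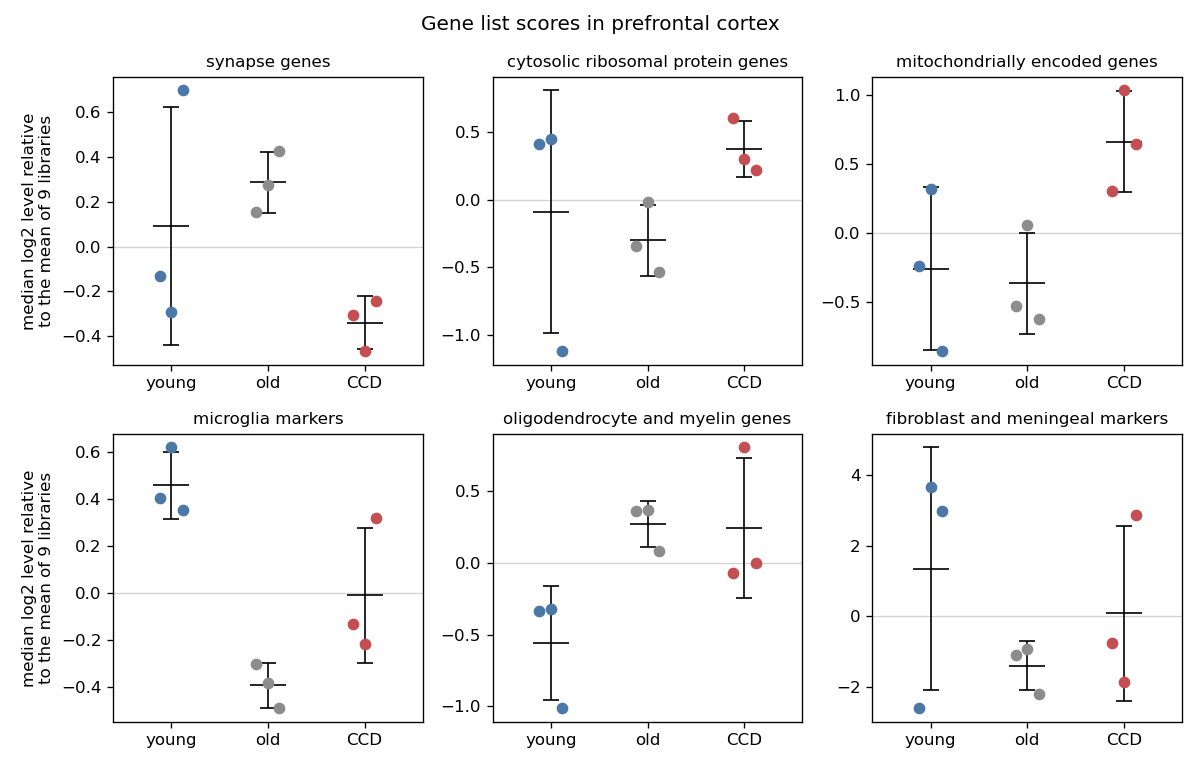
Median log2 level of 6 gene lists in each cortex library, relative to the mean of the 9 libraries (vertical axis), by group (horizontal axis); points are libraries and bars are the group mean with its SD (n = 3). The 3 CCD libraries lie below the 3 old libraries for synapse genes, and the meningeal score is high in young cortex_353 (3.67), young cortex_377 (2.97) and CCD cortex_358 (2.88).

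The second comparison, old against young cortex, asks what differs between old and young dogs (n = 3 per group). The labels give no sex, batch or breed, so these groups may differ in more than age. Microglial, complement, inflammatory and activity-dependent genes fell in old cortex, and myelin genes rose. Microglia markers fell by a median of -0.90 relative to all genes, negative in 22 of 23 (camera adjusted p = 1.9e-13; adjusted p = 0.0636 with an estimated correlation, and 0.0395 in the fit of old and young alone). Tested with fry against no change, rather than against other genes, they had an adjusted p of 0.0344.. When adjusted over the list alone 6 fell, and 0 over all genes, among them PTPRC, the leukocyte phosphatase CD45, at -1.69 ± 0.37, CSF1R, the receptor microglia need to survive, at -0.99 ± 0.26, and GPR34 at -1.36 ± 0.33 (adjusted p = 0.0153 for each over the list alone). Complement genes fell by -1.24 (camera adjusted p = 6.0e-13; adjusted p = 0.183 with an estimated correlation), with C3AR1 at 75.3 ± 18.5 normalised counts in old and 337 ± 85.3 in young (SD), a log2 fold change of -2.14 ± 0.32 (adjusted p = 7.6e-04 over the list alone), and C3 at -1.23 ± 0.27 (0.0102). Immediate early genes, which respond to neuronal activity and stress, fell by -1.06, negative in 25 of 27 (camera adjusted p = 1.4e-13; adjusted p = 0.186 with an estimated correlation). Of these BTG2 was at -1.66 ± 0.48, KLF4 at -2.13 ± 0.64 and EGR2 at -2.88 ± 0.95, and 0 of 27 passed over the list alone.

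Oligodendrocyte and myelin genes rose by a median of 0.81 in old cortex, positive in 18 of 20 (camera adjusted p = 2.1e-11; adjusted p = 0.263 with an estimated correlation). When adjusted over the list alone 9 rose, and 0 over all genes. HAPLN2, a link protein of the node of Ranvier, had 1828 ± 138 normalised counts in old and 504 ± 143 in young (SD), a log2 fold change of 1.89 ± 0.25 (adjusted p = 2.5e-04 over the list alone). ASPA, which breaks down N-acetylaspartate, rose by 1.33 ± 0.29, FA2H, an enzyme of myelin lipids, by 1.31 ± 0.32 and CNP, a myelin enzyme, by 1.03 ± 0.27 (0.00868, 0.0122 and 0.0146 over the list alone). Synapse genes rose by 0.18 (camera adjusted p = 0.0300; adjusted p = 0.701 with an estimated correlation); without young cortex_270, young cortex_353 or old cortex_264 this call ended (0.09, 0.03 and 0.14).

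Inflammatory cytokine and NF-kB genes fell by -1.15 (camera adjusted p = 6.3e-10) and reactive astrocyte genes by -1.12 (7.9e-08), each with an adjusted p = 0.183 with an estimated correlation. CCL2, a monocyte attractant, was at -3.22 ± 0.60 (adjusted p = 0.00623 over the list alone) and TIMP1, a metalloproteinase inhibitor, at -3.75 ± 0.81 (0.00767). Disease-associated microglia genes fell by -0.83 (camera adjusted p = 2.4e-06; adjusted p = 0.183 with an estimated correlation), with GPNMB at -3.34 ± 0.81 (0.0162 over the list alone). Antigen presentation genes fell by -0.81 (3.0e-07; adjusted p = 0.291 with an estimated correlation; -0.44 without young cortex_270) and type I interferon genes by -0.46 (4.6e-04; adjusted p = 0.497 with an estimated correlation; -0.24 and still called without young cortex_353, -0.44 and not called without young cortex_377). Unfolded protein response genes fell by -0.39 (1.1e-04; adjusted p = 0.358 with an estimated correlation), cell senescence and p53 genes by -0.48 (0.00215; adjusted p = 0.433 with an estimated correlation) and heat shock genes by -0.12 (0.00254; adjusted p = 0.601 with an estimated correlation). Without young cortex_270 these 3 calls ended, at -0.21, -0.11 and 0.13. Fibroblast and meningeal markers fell beside them by -2.89, in 14 of 14 members (camera adjusted p = 1.0e-07; adjusted p = 0.433 with an estimated correlation; -1.62 without young cortex_353); without young cortex_353, young cortex_377 and CCD cortex_358, the 3 libraries with a high meningeal score, the value was 1.30, and that of interferon genes was 0.13. However, young cortex_270, the lowest in that score (-2.62), is then the only young library. COL1A1 was at -4.32 ± 1.58. Endothelial markers (-0.63, camera adjusted p = 1.3e-05; adjusted p = 0.497 with an estimated correlation) and pericyte markers (-0.48, 0.0191; adjusted p = 0.566 with an estimated correlation) fell too; the pericyte call ended without young cortex_353 (-0.21), young cortex_377 (-0.22) or old cortex_253 (-0.25), and the median was 0.58 with young cortex_270 as the only young library. Ribosomal protein genes fell by -0.23 (3.5e-04; adjusted p = 0.754 with an estimated correlation), which was 0.04 without young cortex_353, and not called without old cortex_264 (-0.11) or young cortex_270. Platelet genes (-0.21, camera adjusted p = 0.0338; adjusted p = 0.419 with an estimated correlation) and proteasome genes (0.05, 0.0213; adjusted p = 0.720 with an estimated correlation) were called as well. The platelet call ended without young cortex_353 (-0.05), young cortex_377 (-0.36) or old cortex_264 (-0.17), and the proteasome call without young cortex_377 (-0.18), old cortex_250 or old cortex_253 (0.03 for both).

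Gene by gene, limma called 0 of 19010 genes in old against young cortex, with 542 higher and 740 lower at an unadjusted p under 0.05. With edgeR the count was 0 (unadjusted 1531, 387 higher and 1144 lower) and that of DESeq2 216, of which 181 were lower (1815 unadjusted). Without young cortex_377 limma called 41 genes and without young cortex_270 it called 2. Groups did not overlap in 12.2% of genes, where chance gives 10%. Besides HAPLN2 and C3AR1, the genes of smallest p included INHBA, an activin subunit induced by activity (127 ± 24.7 in old, 600 ± 187 in young, SD; log2 fold change -2.20 ± 0.33), DBX2 (-1.52 ± 0.23) and SERPINH1, a collagen chaperone (-3.04 ± 0.50). HRH3, the presynaptic histamine receptor, was at 1.03 ± 0.17, GPD1 at 1.52 ± 0.26 and ARMC3 at 2.46 ± 0.44 (limma adjusted p from 0.196 for INHBA to 0.297 for ARMC3). GFAP was at -0.46 ± 0.24, APOE at -0.14 ± 0.28, APP at 0.31 ± 0.24, MAPT at 0.31 ± 0.19 and TREM2 at -0.82 ± 0.72, none past the test. Without young cortex_353 APP was at 0.11 and MAPT at 0.14, and without young cortex_270 TREM2 was at -0.50. The lower share at an unadjusted p under 0.05 was 57.7% with limma and 44.7% with each library centred on its median gene. In edgeR more genes were lower than higher.

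The third comparison, CCD against young cortex, spans age and disease together (n = 3 per group). Myelin genes rose by a median of 0.83 relative to all genes (camera adjusted p = 2.5e-09) and immediate early genes fell by -0.98 (3.4e-08), each with an adjusted p = 0.811 with an estimated correlation. When adjusted over the list alone 7 of 20 myelin genes rose, including HAPLN2 at 1.34 ± 0.25 and MBP, myelin basic protein, at 1.98 ± 0.69 (1.03 without young cortex_377), and 11 of 27 immediate early genes fell, including NPAS4, a neuron-specific activity factor, at -2.13 ± 0.52 and FOSB at -3.93 ± 1.36 (-1.98 without CCD cortex_354); over all genes the counts were 0. Ribosomal protein (0.54, camera adjusted p = 2.4e-10), oxidative phosphorylation (0.53, 1.2e-07), mitochondrially encoded (1.01, 9.9e-05) and proteasome genes (0.25, 0.0136) rose, each with an adjusted p = 0.811 with an estimated correlation. Unfolded protein response genes (-0.47, camera adjusted p = 2.8e-05), heat shock genes (-0.33, 0.00116), synapse genes (-0.29, 0.00554), amyloid and tau genes (-0.24, 0.00723), histone genes (-0.51, 0.0136), microglia markers (-0.39, 0.0191) and NF-kB genes (-0.73, 0.0191) fell, again each with an adjusted p = 0.811 with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, was at -0.88 ± 0.22, and of the synapse genes HOMER1 (-1.26 ± 0.28) and NPTX2 (-2.24 ± 0.51) fell when adjusted over the list alone (0.0218 for both). SOX9, an astrocyte transcription factor, fell by the same measure (-1.74 ± 0.35; 0.00689), while astrocyte markers as a list did not pass (-0.06, camera adjusted p = 0.230).

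Single libraries decided several of these calls in CCD against young cortex. The myelin median was 0.55 without CCD cortex_354 and the mitochondrial median 0.65 without young cortex_377. Without young cortex_377 the median was 0.02 for ribosomal protein, 0.11 for oxidative phosphorylation and 0.02 for synapse genes, without young cortex_270 it was -0.08 for heat shock genes, and without CCD cortex_163 it was -0.20 for amyloid and tau genes, none then called. The amyloid and tau median was -0.077, still called, without young cortex_377. The microglia call ended without young cortex_270 (-0.23), young cortex_353 (-0.42) or CCD cortex_354 (-0.32), the NF-kB call without young cortex_270 (-0.28), young cortex_353 (-0.49) or CCD cortex_163 (-0.46), the histone call without young cortex_270 (-0.21) or CCD cortex_358 (-0.30), and the proteasome call without young cortex_353 (0.26), young cortex_377 (0.02) or CCD cortex_163 (0.14). limma called 0 of 19010 genes, with 786 higher and 1661 lower at an unadjusted p under 0.05. The edgeR count was 0 (unadjusted 2460, 964 higher and 1496 lower) and that of DESeq2 208, of which 119 were lower (2809 unadjusted). Without CCD cortex_358 limma called 1 gene. Groups did not overlap in 13.5% of genes, where chance gives 10%. The genes of smallest p were IL12RB2, an interleukin 12 receptor chain (239 ± 29.4 in CCD, 76.2 ± 7.84 in young, SD; log2 fold change 1.63 ± 0.26), ARRDC2 (2.22 ± 0.41), CYP27A1, a sterol hydroxylase (1.25 ± 0.26), CXADR, a cell adhesion protein (-1.24 ± 0.21), and IL17RD (-4.27 ± 0.83), with a limma adjusted p of 0.363. GFAP was at 0.01 ± 0.24, APOE at 0.33 ± 0.28, APP at -0.42 ± 0.24, MAPT at -0.31 ± 0.19 and TREM2 at -0.77 ± 0.72, none past the test. Without young cortex_377 APP was at -0.26 and MAPT at -0.13, and without CCD cortex_354 APOE was at 0.18. The lower share at an unadjusted p under 0.05 was 67.9%, 50.1% after quantile normalisation and 48.5% with each library centred on its median gene.

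Transposable elements, repeated sequences that can be transcribed, are counted in the same tables by family and were tested as 700 cortex families apart from the genes. In CCD against old cortex (n = 3 per group) 10 families rose and 1 fell at a limma adjusted p under 0.05, and 172 had an unadjusted p under 0.05, of which 9 were lower. LTR55, an endogenous retroviral repeat, had 318 ± 86.6 normalised counts in CCD and 115 ± 33.4 in old (SD), a log2 fold change of 1.46 ± 0.27 (adjusted p = 0.0350). L1_Cf, a LINE family, rose by 1.10 ± 0.26 and CarLTR3 by 1.73 ± 0.39, while Eulor2A fell by 3.32 on the log2 scale, SE 0.77 (adjusted p = 0.0404 for each). Of 129 LINE families 120 were higher, by a median of 0.47; the medians were 0.33 over LTR families and 0.27 over DNA transposons. The families took 6.66 ± 1.20% of reads in CCD, 4.80 ± 0.373% in old and 5.02 ± 0.748% in young (SD, n = 3); CCD against old had an exact two-sided permutation p of 0.1, adjusted p = 0.338 over 27 tests. The count rested on each library: it was 0 without old cortex_250, old cortex_253, old cortex_264 or CCD cortex_163, 2 without CCD cortex_354 and 86 without CCD cortex_358. In the fit of CCD and old libraries alone it was 83 higher and 6 lower. In CCD against young cortex 2 families rose, CarLTR3 (1.90 ± 0.39) and L1MEj (1.06 ± 0.23), and Eulor2A fell by 3.61, SE 0.77 (adjusted p = 0.0453 for each); the count was 0 without young cortex_270 or CCD cortex_163, 1 without young cortex_377 or CCD cortex_354, 60 without young cortex_353 and 94 without CCD cortex_358. In old against young cortex limma called 0 families, with 13 at an unadjusted p under 0.05.

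**Figure D2:**
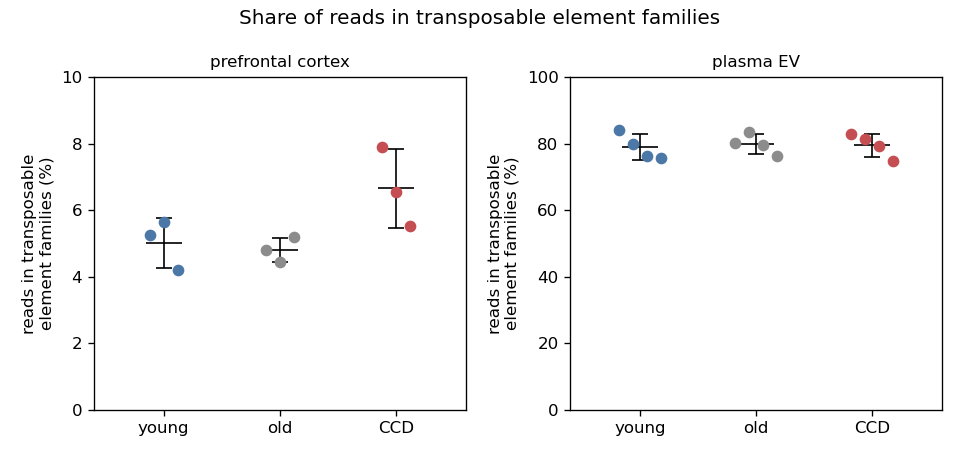
Percent of reads in transposable element families (vertical axis, from 0) in each library of cortex (left) and EVs (right), by group (horizontal axis); points are libraries and bars are the group mean with its SD (n = 3 in cortex, n = 4 in EVs). The CCD cortex mean is 6.66% against 4.80% in old, and the EV libraries lie between 74.9 and 84.2%.

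EV libraries differed from cortex in kind. Transposable element families took 74.9 to 84.2% of EV reads, and mitochondrially encoded genes 0.00105 to 0.0247%. Of the 629 olfactory receptor genes, which serve smell and are expressed mainly in the olfactory epithelium, 95.5 to 100% had reads in each EV library, against 2.23 to 7.63% in each cortex library. The loci LOC119877774 and LOC119877775 together took 0.975 to 5.33% of EV reads.

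The comparison of CCD with old EVs asks whether plasma carries a trace of the disease (n = 4 per group). The median gene was lower in CCD by a log2 change of -0.27, so list values are given relative to it. Values of single genes, here and in the other EV comparisons, still include the shift of the median gene. Mitochondrially encoded genes rose by 1.35 in 6 of 6 members (camera adjusted p = 5.8e-06) and ribosomal protein genes by 0.53 (8.6e-18), each with an adjusted p = 0.969 with an estimated correlation. CYTB was at 1.18 ± 0.86 (0.38 without old EV_519) and RPL19 at 1.14 ± 0.55 (0.69 without old EV_264). Histone genes had a median of 0.27 relative to all genes (camera adjusted p = 0.00292; adjusted p = 0.969 with an estimated correlation), which is 0.00 before the shift of all genes is taken off. The mitochondrial call ended without old EV_519 (0.52), the ribosomal call without CCD EV_523 (0.01), and the histone call without old EV_253 (0.079) or CCD EV_523 (0.075). PANX1, a membrane channel that releases ATP, had 260 ± 45.2 normalised counts in CCD and 561 ± 155 in old (SD), a log2 fold change of -1.08 ± 0.23. NDUFA13, a complex I subunit, had 132 ± 2.97 and 76.7 ± 9.06 (0.78 ± 0.20), SEC11A, a signal peptidase, was at 1.90 ± 0.58, CHEK1, a DNA damage kinase, at 1.18 ± 0.37 and FCN2, a lectin of the complement pathway, at -0.96 ± 0.24 (limma adjusted p = 0.777 for each). GFAP was at -0.44 ± 0.25 (-0.26 without old EV_519), APOE at -0.10 ± 0.54, APP at 0.25 ± 0.21, MAPT at -0.43 ± 0.17 and TREM2 at 0.08 ± 0.40, none past the test. limma called 0 of 31728 genes, with 203 higher and 1693 lower at an unadjusted p under 0.05. With edgeR the count was 0 (unadjusted 1032, 703 higher and 329 lower) and that of DESeq2 2 (1227 unadjusted). Without old EV_253 limma called 1 gene. With a term for the numbers without a cortex library, chosen after seeing the data, limma called 6 genes. At an unadjusted p under 0.05 that fit had 351 higher and 3118 lower. Groups did not overlap in 5.93% of genes, where chance gives 2.86%. The lower share at an unadjusted p under 0.05 was 89.3%, but 34.6% after quantile normalisation and 35.2% with each library centred on its median gene.

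In old against young EVs (n = 4 per group) ribosomal protein genes fell by -0.61 relative to all genes in 75 of 80 members (camera adjusted p = 3.4e-30, and 0.863 with an estimated correlation). Histone genes fell by -0.18 (camera adjusted p = 0.00215, and 0.973 with an estimated correlation). RPLP1 was at -1.36 ± 0.52 and the histone gene H4C8 at -1.51 ± 0.45. The histone call ended without young EV_502 (-0.05) or old EV_253 (-0.09). PANX1 was at 1.10 ± 0.23, TP53BP2 at 0.98 ± 0.30 (0.61 without old EV_264) and the olfactory receptor gene OR5T8 at 1.96 ± 0.65 (limma adjusted p = 1.0 for each). GFAP was at 0.06 ± 0.25, APOE at -0.11 ± 0.54, APP at -0.17 ± 0.21 (-0.022 without young EV_270), MAPT at 0.01 ± 0.17 and TREM2 at -0.17 ± 0.40. limma called 0 of 31728 genes, with 239 higher and 155 lower at an unadjusted p under 0.05. The edgeR count was 0 (unadjusted 591, 218 higher and 373 lower) and that of DESeq2 0 (775 unadjusted). Without old EV_253 limma called 1 gene. Groups did not overlap in 0.917% of genes, where chance gives 2.86%. The lower share at an unadjusted p under 0.05 was 39.3%, 57.3% after quantile normalisation and 51.4% with each library centred on its median gene.

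In CCD against young EVs (n = 4 per group) mitochondrially encoded genes rose by 2.09 relative to all genes, in 6 of 6 members (camera adjusted p = 5.6e-12; adjusted p = 0.454 with an estimated correlation), where the median gene was lower by -0.17. The score of young EV_502 was -2.90 against -1.01 to 0.60 in the other young libraries, and without it the median was 1.43 and CYTB at 1.23. With it CYTB was at 2.06 ± 0.86, ND5 at 2.04 ± 0.74 and ND4 at 1.83 ± 0.76, and 0 of the 6 passed over the list alone. Their share of reads was 0.0189 ± 0.00617% in CCD and 0.00690 ± 0.00557% in young (SD, n = 4), exact two-sided permutation p = 0.0571, adjusted p = 0.514 over 27 tests. KCNIP3, a calcium-binding protein of neurons, was at -0.85 ± 0.21, DCLK3 at -0.75 ± 0.18 and AMT, of the glycine cleavage system, at -0.89 ± 0.25, with FIBCD1 at 1.17 ± 0.44 and TM2D1 at 0.94 ± 0.37 (0.56 without CCD EV_163) on the higher side (limma adjusted p = 1.0 for each). GFAP was at -0.38 ± 0.25, APOE at -0.21 ± 0.54, APP at 0.08 ± 0.21, MAPT at -0.42 ± 0.17 and TREM2 at -0.09 ± 0.40. limma called 0 of 31728 genes, with 43 higher and 861 lower at an unadjusted p under 0.05. With edgeR the count was 0 (unadjusted 521, 251 higher and 270 lower) and that of DESeq2 1 (632 unadjusted). Groups did not overlap in 2.71% of genes, where chance gives 2.86%. The lower share at an unadjusted p under 0.05 was 95.2%, 56.5% after quantile normalisation and 52.9% with each library centred on its median gene. Of 811 transposable element families limma called 0 in each EV comparison, with 80 at an unadjusted p under 0.05 in CCD against old, 29 in old against young and 3 in CCD against young.

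Fold changes in cortex and EVs were then set side by side across the 18741 genes tested in both, to see whether EVs mirror the brain. Pearson's r across genes was 0.00882 for CCD against old (Spearman's rho -0.00216), 0.0452 for old against young (0.0472) and -0.0109 for CCD against young (-0.0328). Against the 20 assignments of the cortex libraries to groups, the exact two-sided permutation p of Pearson's r was 0.4, 0.1 and 0.8 and that of Spearman's rho 1, 0.6 and 0.7. For Pearson's r it was, after adjustment over these 3 comparisons, 0.6, 0.3 and 0.8. Genes are not independent replicates, and 0.1 is the smallest p that these assignments allow. Genomic DNA is a candidate source of the EV reads, as given below. If EV reads came largely from it, a low r could not show whether EV RNA mirrors cortex RNA.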

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

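The tests of explanations in this part were all chosen after the patterns had been seen; the comparison of single libraries with their group followed a rule fixed beforehand. The first pattern is that EV libraries carried reads over nearly every gene. A candidate explanation is genomic DNA in the EV libraries. In cortex the transcript LOC102156855, which lies next to CHIC1 in the UU_Cfam_GSD_1.0 annotation, was at 2267 or more normalised counts in 5 numbers and at 25.6 or less in 4, and the EV level of X-linked genes relative to all others was higher by a log2 difference of 0.52 in the 5 than in the 4 (0.10 to 0.18 against -0.59 to -0.16; exact two-sided permutation p = 0.00794 over 126 assignments), while cortex showed 0.07 (exact two-sided permutation p = 0.778). Such a difference could arise if the copy number of the X chromosome differed between the numbers, as by sex. It would then show in DNA but not in cortex RNA. The 5 high numbers are those of young cortex_270, young cortex_377, old cortex_250, CCD cortex_163 and CCD cortex_354, so the groups were not balanced for this transcript. RNA of blood cells as the main source is argued against, since the median of its marker lists reached at most percentile 70.1 of all EV genes in any library (lowest 42.6), with erythroid genes at 62.0, platelet genes at 61.4 and neutrophil genes at 57.1 against 86.5 for synapse genes.

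The second pattern is the fall of microglial, complement and immediate early genes in old against young cortex, with medians of -0.90, -1.24 and -1.06 relative to all genes. Meningeal tissue in some libraries as the whole cause is argued against: with the meningeal score as a covariate the medians were -0.80, -0.83 and -1.16, each still called (camera adjusted p = 3.0e-10, 2.9e-08 and 6.1e-15). Young cortex_270 as the whole cause is argued against too, since without it they were -0.83, -1.35 and -0.81 (1.3e-09, 4.3e-11 and 7.2e-06). Age stays open as an explanation, as do differences in how or when the cortex was taken, which were not tested; with an estimated correlation all 3 calls end in the fit of 3 groups, and that of microglia stays in the fit of old and young alone (adjusted p = 0.0395).

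The third pattern is the lower level of synapse genes in CCD against old cortex, beside higher ribosomal protein genes. After thinning to 14.9 M reads the synapse median was -0.52 relative to all genes (camera adjusted p = 5.7e-06), as before thinning. Thinning keeps the expected share of each gene, so this argues only against fewer counted reads as such. It cannot decide whether whatever made the CCD libraries shallower also made the pattern. A lower share of neurons alone would raise all glial markers alike. The changes of mean library score, taken relative to all genes, were 0.49 for microglia, 0.08 for oligodendrocytes, 0.02 for precursors and 0.01 for astrocytes. The largest and smallest of these 4 differed by 0.49, SE 0.142. That pair was picked for being farthest apart, which the SE does not take in. Whether a lower share of neurons alone explains the pattern therefore stays open. RNA quality or tissue composition that varies in every group may account for it: over the 6 young and old libraries, where no dog had CCD, the synapse and ribosomal protein scores had a Pearson's r of -0.949 (exact permutation p = 0.00972), a Spearman's rho of -0.943 (exact permutation p = 0.0167) and an r of -0.860 without the 2 farthest libraries, the 1 relation computed. Disease stays open as an explanation.

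Single libraries that stood apart from the other 3 of their EV group were found in 10 of 147 groups tested (6.80%), and chance gives about 1 in 20. The share of ribosomal protein reads was 0.0884% in old EV_264 against 0.111 to 0.115% in the others. The share of olfactory receptor genes with reads was 96.3% in young EV_502 (others 99.5 to 100%), 97.3% in old EV_519 (99.7 to 100%) and 95.5% in CCD EV_523 (99.5 to 99.8%), which are the 3 numbers without a cortex library. The log2 level of ND3 was 4.03 in young EV_502 (others 6.36 to 6.66) and that of TP53BP2 was 9.94 in old EV_264 (8.41 to 8.51). In old EV_519 OR5T8 was at 7.04 (4.92 to 5.19) and KCNIP3 at 7.74 (7.30 to 7.31), and in old EV_253 TM2D1 was at 5.87 (6.04 in the others) and DCLK3 at 7.79 (8.01 to 8.04). Over 117 pairs of a list and a comparison, 1 had scores as deposited that separated the groups in opposite directions in the tissues: the microglia score in CCD against old was 0.38 higher in cortex and lower in EVs (-0.33), a difference that was not tested. Relative to the median gene of each library 0 pairs did so. This rule was restated after its first result had been seen, because its first form took separation from scores as deposited and direction from values relative to all genes; that form had found 2 pairs, microglia markers and the amyloid and tau pathway in CCD against old (relative medians -0.01 and 0.02 in EVs).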

How the results depend on the processing

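Alternatives chosen after seeing the data were thinning, centring on the median gene, both covariates, scaling to gene or transposable element reads, the set of 3 libraries left out and the term for numbers without a cortex library; all values for transposable element families were added after seeing the data too. No paired analysis was possible because the groups compared within a tissue share no number. Of 381 alternative values of counts and correlations 302 stayed, which means within 1.5 times for a count and the same sign for a correlation. Of 966 list values 870 kept both their direction and their side of the threshold, and so did 3028 of 3229 values of genes taken by the naming rule. The direction turned in 15 list values and 56 gene values. Since 0 genes passed in the fit of 3 groups, a gene value that stayed had still not passed. Of 126 values of the unadjusted counts 80 stayed near and 46 moved by over 1.5 times. Some 1 library made 34 of 53 list values and 38 of 174 gene fold changes over 1.5 times smaller when left out, or turned them. The cause of a change was not tested unless stated. Thinning left 0 genes called in each comparison, moved lists in old against young from 19 to 20 in cortex and from 2 to 3 in EVs, and moved unadjusted counts a little. Genes called in cortex, 0 in each comparison, were 1778 in CCD against old in the fit of those groups alone, 1632 with library weights and 162 with DESeq2; without the libraries high in meningeal markers they were 2922 in CCD against old, 617 in old against young and 647 in CCD against young, and with DESeq2 216 and 208 in the latter 2. Without those libraries only 1 young cortex library is left, so the values against young rest on that library, with the spread from the other groups. In CCD against old the fold changes are those of leaving out CCD cortex_358 alone (median -0.14), which called 0 genes. The 2 fits differ in whether young cortex_353 and young cortex_377 enter the estimate of spread. The 2922 therefore cannot be credited to the removal of meningeal tissue. The same holds for families, 228 against 86 without CCD cortex_358 alone. Genes called in EVs, also 0, were 2 in CCD against old and 1 in CCD against young with DESeq2, and 6 in CCD against old with a term for the numbers without a cortex library. Leaving out 1 library gave 0 genes in cortex CCD against old, 0 to 41 in old against young and 0 to 1 in CCD against young, and in EVs 0 to 1, 0 to 1 and 0. Families called in cortex CCD against old, 11, were 0 with no filter and with LOC102156855 as a covariate, 19 after quantile normalisation, 89 in the fit of those groups alone, 272 with library weights, 17 thinned, 2 scaled to transposable element reads, 34 with the meningeal covariate and 228 without the meningeal-high libraries. In CCD against young, 3, they were 0 with no filter, a mean of at least 50, scaling to counts-per-million, the fit of those groups alone, scaling to transposable element reads and both covariates, 57 with library weights, 16 centred and 49 without the meningeal-high libraries. In EV old against young they were 33 with library weights. Leaving out 1 library gave 0 to 86 families in CCD against old cortex, 0 to 94 in CCD against young and 0 in old against young and in EVs. In the fit of 3 groups, lists called were 0 in all 6 comparisons with an estimated correlation, and with fry 0 in all but old against young cortex, where 1 passed; both take in the correlation among members, and fry tests against no change rather than other genes. In the fit of the compared groups alone an estimated correlation left 1 list in old against young cortex, and fry called 2 in CCD against old cortex, 3 in old against young cortex and 6 in CCD against old EVs. They were 8 in CCD against old cortex without the meningeal-high libraries. In EVs, CCD against old, old against young and CCD against young, they were 0, 6 and 4 with library weights and 1, 4 and 2 without the numbers that have no cortex library; they were 2 in CCD against young after quantile normalisation and 1 in old against young with a mean of at least 50. Leaving out 1 library gave 8 to 19 lists in CCD against old cortex, 17 to 19 in old against young and 10 to 17 in CCD against young, and in EVs 1 to 4, 1 to 8 and 1 to 3. The correlation of cortex and EV fold changes in CCD against old was -0.0201 with the numbers that have both libraries. Lists that turned were, with the meningeal covariate and without the meningeal-high libraries, endothelial markers in CCD against old (-0.14 and -0.035), pericyte markers in old against young (0.45 and 0.58) and proteasome genes in old against young (-0.11 and -0.33); without those libraries also meningeal markers (1.30) and interferon genes (0.13) in old against young and proteasome genes in CCD against young (-0.12); and with library weights proteasome genes in old against young (-0.034). Genes that turned in cortex were, without the meningeal-high libraries, DCN (0.33) and APOE (0.019) in old against young and TREM2 in CCD against old (-0.10), and GFAP in CCD against young (-0.18), which was -0.083 after quantile normalisation, -0.063 with library weights and -0.029 with the meningeal covariate. In EV CCD against old APOE was 0.20 after quantile normalisation, 0.020 with library weights, 0.16 centred and 0.12 without the numbers that have no cortex library, and TREM2 -0.15 with library weights. In EV old against young, in the same order, GFAP was -0.012, -0.10, -0.026 and -0.22 and MAPT -0.026, -0.047, -0.077 and -0.071; TREM2 was 0.44 with library weights and 0.0086 without those numbers. In EV CCD against young APOE was 0.014 after quantile normalisation, TREM2 0.075, 0.28, 0.083 and 0.051 in the same order, and APP -0.073 without those numbers. With 1 library left out, values that turned ranged in CCD against old cortex from -0.58 to 0.82 for TREM2 and -0.035 to 0.61 for endothelial markers; in old against young from -0.32 to 0.13 for heat shock, -0.73 to 0.039 for ribosomal protein and -0.18 to 0.29 for proteasome genes and -0.27 to 0.077 for APOE; and in CCD against young from -0.51 to 0.018 for synapse genes, -0.16 to 0.13 for GFAP and -1.40 to 0.0065 for TREM2. In EVs they ranged in CCD against old from -0.47 to 0.37 for APOE and -0.21 to 0.33 for TREM2; in old against young from -0.38 to 0.12 for TREM2, -0.59 to 0.25 for APOE, -0.12 to 0.26 for GFAP and -0.075 to 0.044 for MAPT; and in CCD against young from -0.32 to 0.17 for TREM2, -0.033 to 0.22 for APP and -0.55 to 0.13 for APOE.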

Other observations

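The tests of transposable element families, of splits of families and of splits in the fit of 2 groups alone, and the 2 tests of explanations for them, were chosen after the results had been seen, and the genes of the DNA test were chosen anew after its first result. Gene groups that were not called in CCD against old cortex (n = 3 per group) had these medians relative to all genes. Among cell types, astrocyte markers were at 0.02, oligodendrocyte and myelin genes at 0.09, oligodendrocyte precursor markers at -0.18, pericyte markers at 0.35 and choroid plexus markers at -0.33. Among blood cells, erythroid genes were at -0.10, platelet genes at 0.47 (camera adjusted p = 0.0609), neutrophil and monocyte genes at -0.33 and lymphocyte genes at 0.41. Cholesterol synthesis genes were at -0.21 (camera adjusted p = 0.0784), with 17 of 23 negative. Alzheimer's disease risk genes were at 0.04, autophagy and lysosome genes at -0.02, vesicle marker genes at -0.12, liver secreted protein genes at 0.91 (camera adjusted p = 0.398), with 6 of 11 positive and a mean log2 fold change of 0.10, unfolded protein response genes at -0.17 and heat shock genes at -0.09. Proteasome genes were at 0.08, senescence and p53 genes at 0.08, circadian clock genes at -0.15, glucocorticoid response genes at 0.10, hypoxia genes at -0.13, histone genes at -0.28 and immediate early genes at 0.00. APH1B, a gamma-secretase subunit among the risk genes, was at -2.85 ± 0.72 and SOX9 among the astrocyte markers at -1.25 ± 0.35, neither past the limma test over all genes (adjusted p = 0.290).

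Cortex and EV libraries of the same number were compared over 18741 genes, after taking off the group means. Their mean Pearson correlation across genes was 0.0270, from -0.0250 to 0.104 over the 9 numbers, and 10 of the 216 arrangements of numbers within groups gave as much (exact one-sided permutation p = 0.0463; highest other 0.0398). In 6 of 9 numbers the cortex library matched the EV library of its own number best within its group.

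A candidate explanation for the higher transposable element families in CCD against old cortex is the lower depth of the CCD libraries. The median log2 fold change over families was 0.34 after thinning and 0.33 before. Thinning keeps the expected share of each family, so this argues only against fewer counted reads as such, and not against whatever made those libraries shallower. Genomic DNA carried into the CCD libraries stays open: the 7908 genes with reads in EVs and a mean under 1 in young cortex had a normalised total of 4536 ± 996 (SD, n = 3) in CCD and 3418 ± 699 in old (n = 3), a difference of 1118, SE 703, which does not decide. A first choice of 7662 genes with a mean under 1 over all cortex libraries had given a difference of -454, but that choice had left out genes for being higher in CCD. The olfactory receptor genes went the other way. Of the 629, 14, 26 and 18 had reads in the CCD cortex libraries and 41, 34 and 43 in the old ones. The CCD libraries were also shallower, so these counts do not decide either.

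The 3 against 3 libraries of a cortex comparison can be split in 10 ways, too few for a share under 0.05. In CCD against old the real split gave 2815 genes at an unadjusted p under 0.05 and the highest other 563, 15 lists and 22, 11 families and 0, and in the fit of these groups alone 1778 genes and 2. In old against young it gave 1282 genes and the highest other 2538, 19 lists and 19, and 13 families at an unadjusted p under 0.05 and 87 (8 splits gave as many families). In CCD against young it gave 2447 genes and 2958, 13 lists and 21 (6 splits gave as many lists), and 3 families and 3. The 4 against 4 libraries of an EV comparison make 35 splits, and chance could not be excluded for any EV count. In CCD against old 7 splits gave as many genes (1896 real, highest other 6884), 26 as many lists (3 and 14) and 3 as many families (80 and 140). In old against young these were 28 splits (394 genes and 13811), 25 (2 lists and 10) and 9 (29 families and 326). In CCD against young they were 14 (904 genes and 9861), 35 (1 list and 13) and 33 (3 families and 434). Splits that call several times the real count point to a structure of the EV samples other than the groups. The first principal component, 53.1% of the variance, has young EV_502 (153), CCD EV_523 (141) and old EV_519 (97.8) at one end. At the other end are young EV_270 (-120) and old EV_253 (-113). The median normalised count of olfactory receptor genes was 8.64, 9.45 and 14.8 in the former libraries and 49.2 and 45.2 in the latter. This relation was not tested. The splits were free to place libraries of one end on the same side, so their counts carry that structure. Splits that keep them apart were not run.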
